A study of Mus musculus with 6 samples.

How the data were processed

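RNA was measured in 6 libraries of mouse cortical neurons, 3 exposed to a lentivirus carrying N40K and 3 exposed to the vector control, per the labels. Per the labels' protocols, poly(A) RNA was made into stranded libraries and sequenced as paired reads of 100 nt. The submitters' processing notes name CASAVA, STAR, BWA and bedtools 2.16.1 and the mouse build mm9, with no role or order.

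The authors deposited 1 table, which holds a score named Sd, read here as splicing deficiency, for 15705 genes in each library. The deposited values behave as a linear ratio: none is negative, the lowest is 0.0001, and all have 4 decimals. The formula of the score, its gene annotation, its filters and its use of strand are not given in the sources used here. In this field such a score sets reads from unspliced RNA against reads from spliced RNA of the same gene, and a higher score then stands for less complete splicing. A score of this kind cannot separate more unspliced RNA from less spliced RNA. Read totals are not given, so the depth behind each score is unknown and no interval that needs it is printed. The last decimal limits the precision of the lowest scores, such as those of Uqcr11, Mtap1b and Rims2.

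Each column was assigned to its library by its name, and 0 columns of values were left unused. No 2 columns were identical. The scores were tested as log2(score + 0.01) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), 2-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The planned filter, a score in all libraries and above 0 in at least 3 of them, removed no gene. A log2 change on this scale understates the change of genes with low scores, so the ratio of mean scores is given beside it. "Rose", "fell" and "changed" refer to the scores as deposited, without scaling between libraries, and to genes with an adjusted p under 0.05.

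Library medians, and the per-library rank correlation of score with gene length, were compared by an exact permutation test of the 20 assignments, 2-sided, whose smallest p is 0.1. The 19 gene lists were written before the data were examined, as were the main test, the rule for named genes and most alternatives. They held 762 entries, of which 49 had no score. Each list was tested with camera (limma) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 19 lists. Camera compares the genes of a list with all other genes, so its direction is relative. It was also run with an estimated correlation, and fry was run as a test of the list by itself. Fry used the scores as deposited, so a shift over all genes also counts towards its calls. Camera calls after centring or quantile normalization used the preset correlation.

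The genes named by rule were the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, up to 3 called members with the smallest p in each list, and Snrnp70, Snrpa, Snrpc and Camk2a. This gave 75 genes, some of which are not reported here. Other genes are named where a count is small, and were chosen after their values were seen.

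Gene lengths, intron numbers and overlaps came from the GENCODE mouse release M21, which is on another build than mm9. It was matched by Ensembl gene identifier for 14911 genes (94.9%), and no coordinates are printed. By this annotation 8829 of the genes overlap another gene, including 50 of the 75 named genes, and reads in a shared stretch can count for either gene if strand was not used. Ribosomal protein genes have many processed pseudogenes, so their scores are uncertain where reads were shared with them.

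The steps were tested on simulated data. For the comparison of N40K with control, 200 of 15705 genes were given a change: 16% were recovered at a log2 size of 0.25, 54% at 0.5, 70% at 1 and 92% at 2, with 4 false calls among 15505 unchanged genes. A simulated shifted list was called, and 0 of 20 unshifted lists were. Genes were simulated independently of each other, so this does not test list calls where the genes of a list vary together. In the data the estimated correlation was 0.41 for the glutamatergic synapse list.

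The alternatives were pseudocounts of 0.001 and 0.1, no filter, a filter without the lowest 25% of genes by mean score, each library left out, centring each library on its median, quantile normalization, the replicate number as a block, other settings of eBayes, arrayWeights, a threshold of 1.5-fold, and other list tests. Added after seeing the data were a fit without a pseudocount on genes with a mean score of at least 0.002, a fit without overlapping genes, and centring each library on the median deviation of its genes, alone or without a pseudocount. Also added was camera on the gene lists after the trend of change with gene length and score level (loess, span 0.3) was removed, over genes with a known length; for the glutamatergic synapse and ion channel lists this test was set beforehand. The reading of the scaling test was changed after its value was seen: the script first counted any low share of rises after centring in favour of scaling, and now does so only if the test of a single factor allows it. The value for that test was first taken from library medians and then from deviations of genes from their means. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.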

Results

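RNA sequencing was used to compare splicing across the genes of neurons that received N40K and neurons that received a control vector. N40K is the N-terminal fragment of U1-70K, the protein encoded by Snrnp70. U1-70K belongs to the U1 snRNP, the complex that recognises the start of introns, and the series asks how its disturbance in Alzheimer's disease affects neurons. Cortical neurons were taken from C57BL/6 mouse embryos at embryonic day 18, cultured for 7 days and exposed to lentivirus for 3 days. The control virus carried EGFP under a short CaMKII promoter, and the other virus carried N40K. Each group had 3 libraries, and the deposited data give 1 splicing deficiency score for each of 15705 genes in each library. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Scores ranged from 0.0001 to 2886.7, and their depth is unknown. Across genes, which are not independent replicates, libraries of the same group correlated with a Spearman rho of 0.983 to 0.987, and libraries of different groups with a rho of 0.957 to 0.969.

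Neurons with N40K had higher scores than control neurons for many genes. Of the 15705 genes, 3372 rose and 645 fell with N40K (limma, Benjamini-Hochberg adjusted p under 0.05). The ratio of mean scores had a median of 1.71 among the rises and 0.62 among the falls, and 1017 rises and 156 falls were at least 2-fold. All 3 N40K scores lay above all 3 control scores for 5282 genes (33.6%) and below them for 1362 genes (8.67%), where chance gives 5% in each direction and 10% in all. The median score of a library was 0.0132 ± 0.0005 in control neurons and 0.0154 ± 0.0009 in N40K neurons (SD, n = 3), a ratio of 1.17, with an exact permutation p of 0.1, the smallest the design allows. The division into rises and falls depended on scaling. Centring each library on its median removed a shift of 0.13 (log2) and gave 1531 rises and 2883 falls. The median change of a gene was 0.06 (log2), so this centring by itself moved the typical gene below 0. Quantile normalization gave 2022 and 1883. Centring on the median deviation of the genes, chosen after seeing the data, gave 2235 and 1518. The same without a pseudocount, also chosen afterwards, gave 2190 and 1202 of 14306 genes. The count of 4017 changed genes moved to 2331, 2015 and 1947 without control replicates 1, 2 and 3, to 2424 without N40K replicate 2, to 2451 under the stricter filter, to 951 at a threshold of 1.5-fold, and to 1182 of 6082 genes that overlap no other gene.

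The largest rises were in genes with mean control scores of at most 0.043. Sh3tc1 rose from 0.00927 ± 0.00687 to 0.256 ± 0.0619 (mean ± SD, n = 3), a log2 change of 3.83 ± 0.32 (SE). Abcc10, a transporter of the multidrug resistance family, rose from 0.029 ± 0.00639 to 0.313 ± 0.031. Pappa2, a protease that cleaves insulin-like growth factor binding proteins, rose 18.6-fold, and P2rx5, an ATP-gated ion channel, rose 9.24-fold. Large rises were also found in Sec14l5, Loxhd1, Aox3l1, Dgat2l6, 1700123I01Rik, F630043A04Rik and 4933437F05Rik, with ratios from 7.04 for Dgat2l6 to 17.2 for 1700123I01Rik. The largest fall was in Gnmt, the glycine N-methyltransferase gene, from 2.38 ± 0.51 to 0.411 ± 0.0294, a log2 change of -2.49 ± 0.17. Cldn15, a claudin of tight junctions, had a ratio of 0.187, Havcr2, an immune receptor, 0.177, and the secreted phospholipase gene Pla2g3 0.262. Rdh16, 9130024F11Rik and C030030A07Rik also fell, with ratios of 0.228, 0.229 and 0.232. Limma adjusted p-values of the genes named so far lay between 0.000916 for Abcc10 and 0.0125 for Havcr2. Zfp300, Trim5, Vpreb3 and Scx were also among the 12 largest falls, but their calls ended without certain libraries: Zfp300 without control 1, control 2 or N40K 2 (highest adjusted p = 0.0648), Trim5 without any library other than control 1 (0.108), Vpreb3 without control 3 or any N40K library (0.0755), and Scx without any library other than N40K 1 (0.115). By annotation, 7 of the 12 rises and 8 of the 12 falls overlap another gene.

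Many genes of glutamatergic synapses and voltage-gated ion channels rose in N40K neurons. Of 51 glutamatergic synapse genes, 25 rose, 2 fell and the others did not pass; 35 rose and 3 fell when adjusted over the list alone. Homer1, a postsynaptic scaffold and an activity-induced gene, rose from 0.005 ± 0.0001 to 0.0183 ± 0.00182 (limma adjusted p = 0.00154), and the AMPA receptor subunit gene Gria3 rose from 0.00177 ± 0.000208 to 0.0039 ± 0.000346 (0.0034). Homer2 rose 1.85-fold, and the falls were in the glutamate receptor genes Grm2 and Grin2d, named after their values were seen, with ratios of 0.735 and 0.559. Of 58 channel genes, 31 rose and 0 fell, or 33 and 0 adjusted over the list alone. Kcnc4, a fast-inactivating potassium channel, rose from 0.0168 ± 0.0024 to 0.0491 ± 0.0033, the sodium-activated potassium channel gene Kcnt2 rose 2.4-fold, and Cacnb4, an auxiliary calcium channel subunit, rose 2.29-fold. The lists had a median log2 change of 0.10 and 0.08, and camera called both as higher than other genes (adjusted p = 0.000623 each). With an estimated correlation neither call held (adjusted p = 0.696 each). Both calls also ended under the stricter filter (0.769 for the glutamatergic synapse list and 0.379 for the voltage-gated ion channels list) and without overlapping genes (0.0788 and 0.582). They ended as well after centring each library on its median (0.907 and 0.571) and after the trend of change with gene length and score level was removed (0.654 and 0.474). The stricter filter left 17 and 20 genes of these lists, with medians of 0.082 and 0.079. Leaving out overlapping genes left 10 and 18, with medians of 0.084 and 0.028. Fry, which tests a list by itself and so includes the shift over all genes, called both lists higher (adjusted p = 0.0172 and 0.0132). With each library centred on its median, 4 glutamatergic synapse genes rose and 10 fell, and 6 channel genes rose and 11 fell. Rises outnumbered falls after quantile normalization (14 and 6, and 19 and 5), where camera called both lists higher (0.0115 and 0.00519), and after centring on the median deviation (9 and 6, and 19 and 5), where it called neither (0.0607 each). Without a pseudocount, a fit chosen after seeing the data, 35 and 44 genes of these lists were left. Camera at the preset correlation called both lists higher in that fit (adjusted p = 0.00617 and 0.00441). With centring on the median deviation added, it also called both (0.0108 and 0.00493), with 15 rises and 3 falls, and 19 and 1. Without control 2, 10 genes of each list rose, and with the eBayes trend off 13 glutamatergic synapse genes and 20 channel genes rose. The call of Homer2 ended after centring each library on its median (limma adjusted p = 0.238) but held after quantile normalization (0.0104).

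Camk2a, the gene of a kinase of excitatory neurons, rose from 0.00313 ± 0.000116 to 0.00473 ± 0.000513, but the call ended without control 2 (limma adjusted p = 0.0537) or control 3 and after centring each library on its median (0.279). Of 42 genes of GABAergic synapses and interneurons, 7 rose and 0 fell, or 5 and 0 adjusted over the list alone, among them Lhx6, a transcription factor of interneurons (1.95-fold), the trafficking adaptor gene Trak1 (1.56-fold) and the calcium buffer gene Pvalb (1.55-fold). Of 46 genes of synaptic vesicles and release, 5 rose and 3 fell, or 4 and 3 adjusted over the list alone. The active zone scaffold gene Bsn fell from 0.0356 ± 0.00191 to 0.0214 ± 0.000208 (adjusted p = 0.00419) and Syt11 fell from 0.00633 ± 0.000153 to 0.0044 ± 0.0001 (0.0049). The other fall was in Atp6v0a1 and the other rises were in Pclo, Amph, Syn1 and Rab3c, named after their values were seen. Rims2 rose 2.3-fold, a call that ended without control 2 or control 3 (highest adjusted p = 0.0574). Of 47 cytoskeleton and axon genes, 6 rose and 0 fell, or 4 and 0 adjusted over the list alone, with Mtap6, a microtubule-stabilising protein gene, up 1.99-fold and Mtap1b up 1.86-fold; Kif1b rose 1.38-fold, a call that ended without control 2, control 3 or N40K 2 (highest adjusted p = 0.0662). With a library left out, 4 to 11 GABAergic, 0 to 12 vesicle and 2 to 6 cytoskeleton genes rose. With scores as deposited these 3 lists were not called by camera at the preset correlation (adjusted p = 0.826, 0.652 and 0.213) or at an estimated one (0.931, 0.931 and 0.789). After centring each library on its median the balance turned: 21, 29 and 23 genes of these lists fell and 2, 0 and 1 rose, and camera called all 3 lower than other genes (0.000383, 2.67e-05 and 3.95e-05), as it did after quantile normalization (0.0275, 0.0118 and 0.00179) and centring on the median deviation (0.002, 9.5e-05 and 9.52e-05). With the latter and no pseudocount, 5 of 27, 4 of 28 and 2 of 32 genes fell and 3, 1 and 3 rose. Scores well under the pseudocount change little on the log2 scale, so subtracting a shift can turn their rises into falls. With each library centred on its median, the calls of Pvalb, Rims2, Mtap1b and Kif1b ended (limma adjusted p = 0.895, 0.547, 0.0682 and 0.0956), and all but that of Pvalb turned in direction. After quantile normalization none of these genes turned, and Rims2 kept its call (0.0102) while the others lost it (0.118, 0.057 and 0.365).

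Among splicing factors, Snrnp70 itself did not pass the test. Its score was 0.0216 ± 0.000656 in control neurons and 0.0233 ± 0.000902 in N40K neurons (limma adjusted p = 0.376); the labels do not say whether N40K reads could count towards it. Snrpa, at 0.0025 ± 0.0003 and 0.00193 ± 0.000231, and Snrpc, at 0.0123 ± 0.0018 and 0.00877 ± 0.00156, also did not pass (0.0941 and 0.0898), but passed as falls after centring each library on its median (0.0115 and 0.0209). Of 11 genes of the U1 snRNP and Sm proteins, 0 rose and 2 fell, also when adjusted over the list alone; after centring each library on its median 0 rose and 8 fell. The Sm protein gene Snrpg fell from 0.00783 ± 0.000451 to 0.00503 ± 0.000208, and Snrpf had a ratio of 0.739, a call that ended when any library other than control 2 was left out (highest adjusted p = 0.0929). Camera called this list lower than other genes (adjusted p = 0.0281), a call that ended without N40K replicate 2 (U1 snRNP and Sm proteins list, 0.0608), without overlapping genes (0.306), with an estimated correlation (0.588) and after the trend with gene length and score level was removed (0.474). Of 45 other core spliceosome genes, 7 rose and 2 fell, or 6 and 1 adjusted over the list alone: Crnkl1 rose 2.39-fold, Aqr, a helicase that binds introns, 1.68-fold, and Lsm7, of the U6 snRNP, fell to a ratio of 0.524, as did Prpf38b, named after its value was seen, to 0.804. Of 60 SR proteins and splicing regulators, 16 rose and 2 fell, or 18 and 2 adjusted over the list alone. Tardbp, which encodes TDP-43, rose from 0.00363 ± 0.000305 to 0.0085 ± 0.0002, the neuronal splicing repressor gene Ptbp2 from 0.00627 ± 0.000153 to 0.016 ± 0.00203, and Hnrnpd 1.86-fold; Tra2a and Srsf9, named after their values were seen, fell to ratios of 0.557 and 0.768. Neither list was called by camera (adjusted p = 0.466 and 0.691), and fry called the regulators higher (0.0498). After quantile normalization camera called the other core spliceosome list lower (0.0248). With a library left out, 3 to 6 core spliceosome genes and 4 to 17 regulators rose, and with the eBayes trend off 7 and 8 rose. After centring each library on its median, 11 core spliceosome genes and 17 regulators fell and 3 and 4 rose, and the call of Aqr ended (adjusted p = 0.534). With centring on the median deviation and no pseudocount, 4 of 44 core spliceosome genes and 9 of 51 regulators fell and 4 and 6 rose. In that fit 4 of 9 U1 snRNP and Sm protein genes fell and 0 rose.

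Genes of the ribosome and of oxidative phosphorylation, most of them short, showed few rises. Of 75 ribosomal protein genes, 1 rose and 8 fell, or 0 and 4 adjusted over the list alone. Rps28 fell from 0.00307 ± 0.000116 to 0.0012 in all 3 N40K libraries (limma adjusted p = 0.0013), Rps26 fell to a ratio of 0.548 and Rpl37a to 0.674, and the rise was in Rpl39, named after its value was seen (1.71-fold). Of 75 oxidative phosphorylation genes, 1 rose and 4 fell, or 1 and 2 adjusted over the list alone. Uqcr11, a subunit gene of complex III, fell from 0.000967 ± 0.000116 to 0.0005; Ndufc1, of complex I, had a ratio of 0.593, a call that ended without control 1 or control 2 (highest adjusted p = 0.0554). Cox7b and Ndufa2, named after their values were seen, had ratios of 0.714 and 0.792. Ndufa11 rose 1.39-fold, a call that ended without control 2 or control 3 (0.0546) and after centring each library on its median (0.151). Camera called both lists lower than other genes (adjusted p = 4.78e-05 and 3.06e-05), and neither call held with an estimated correlation (adjusted p = 0.292 and 0.588); the second also ended under the stricter filter (oxidative phosphorylation, 0.084). Both ended after the trend with gene length and score level was removed (0.654 and 0.788), and the camera direction of the second turned to higher. Fry called the ribosomal protein list lower (adjusted p = 0.00985). Their median log2 changes were -0.01 each, and after centring each library on its median 19 and 47 of their genes fell and 0 rose. With centring on the median deviation and no pseudocount, 8 of 71 and 9 of 52 fell and 0 and 1 rose. With a library left out, 3 to 7 ribosomal protein genes and 1 to 3 oxidative phosphorylation genes fell.

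The lists of cell death, Alzheimer disease, activity and interferon genes were not called by camera with scores as deposited. Of 36 genes of p53, apoptosis and stress response, 9 rose and 0 fell, or 9 and 1 adjusted over the list alone, and 5 to 8 rose with a library left out. The pro-apoptotic p53 target Bbc3 rose from 0.017 ± 0.00231 to 0.0715 ± 0.00925 (limma adjusted p = 0.00174), and the initiator caspase gene Casp8 rose from 0.017 ± 0.00142 to 0.0661 ± 0.0185 (0.00557). Of 31 Alzheimer disease genes, 4 rose and 0 fell, or 3 and 0 adjusted over the list alone. Among them, the alpha-secretase gene Adam10 rose 2.59-fold, the insulin-degrading enzyme gene Ide 1.47-fold, and Sorl1, named after its value was seen, 1.26-fold. After centring each library on its median the calls of Adam10 and Ide ended (adjusted p = 0.119 and 0.151), and 12 Alzheimer disease genes fell and 1 rose. The same centring gave 4 rises and 5 falls for p53, apoptosis and stress response, 1 and 7 for immediate early genes, and 1 and 5 for interferon response. For p53, apoptosis and stress response quantile normalization gave 6 and 5 and centring on the median deviation 5 and 5. With the latter and no pseudocount, rises and falls were 2 and 1 of 24 Alzheimer disease genes and 6 and 3 of 34 for p53, apoptosis and stress response. They were 2 and 7 of 23 immediate early genes and 1 and 1 of 33 interferon response genes. The scores of Adam10 and Ide lay below the pseudocount, and their log2 changes with it were 0.188 and 0.195. Of 23 immediate early genes, 4 rose and 1 fell, the same counts as adjusted over the list alone; beside Homer1, the neurotrophin gene Bdnf rose 2.39-fold and the transcription factor gene Egr3 fell from 0.0201 ± 0.000153 to 0.0118 ± 0.0021. The other rises were in Inhba and Maff, named after their values were seen, and the call of Bdnf ended after centring each library on its median (adjusted p = 0.112). Of 33 interferon response genes, 1 rose and 1 fell, also adjusted over the list alone. Parp9 fell to a ratio of 0.538, a call that ended without control 1 or control 2 (highest adjusted p = 0.0548). Camera called none of these 4 lists (adjusted p = 0.821, 0.821, 0.0523 and 0.0523), and fry called the list of p53, apoptosis and stress response higher (0.00985).

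Few markers of other cell types passed the test with scores as deposited. The microglia list and the endothelial and mural list had median log2 changes of 0.24 and 0.20, against 0.06 over all genes. Of their genes, 8 of 11 and 13 of 16 were higher in N40K, passing or not. The astrocyte and progenitor lists had medians of -0.007 and -0.038. Of 20 astrocyte markers, 1 rose and 0 fell, or 0 and 0 adjusted over the list alone: the glutamate transporter gene Slc1a2 had a ratio of 1.19, a call that ended when any 1 of the 6 libraries was left out (highest limma adjusted p = 0.13) and turned, without passing, after centring each library on its median. Of 11 microglia markers, 2 rose and 0 fell, with the same counts adjusted over the list alone. They were Csf1r (2.76-fold), lost without control 3 (0.0536), and Itgam (2.71-fold), lost without control 1 or control 3 (highest adjusted p = 0.0635). Of 14 oligodendrocyte lineage markers, 1 rose and 1 fell, also adjusted over the list alone: Enpp6 rose from 0.0033 ± 0.00161 to 0.0445 ± 0.0181, and the myelin gene Mog had a ratio of 0.729, lost without control 1, control 2 or N40K 3 (highest adjusted p = 0.0683). The list had a median log2 change of -0.03 and a mean of 0.12. Of 16 endothelial and mural markers, 2 rose and 1 fell, also adjusted over the list alone. Esam rose 2.03-fold. Eng, at 2.75-fold, lost its call when any library other than control 3 was left out (highest adjusted p = 0.0881), and Vwf, at a ratio of 0.37, without control 2, control 3, N40K 2 or N40K 3 (0.0968). Of 18 progenitor and proliferation markers, 0 rose and 0 fell, also adjusted over the list alone. Camera called the progenitor and proliferation markers lower than other genes (adjusted p = 0.0232), a call that ended without N40K 2 (0.0528), without N40K 3 (0.0716), under the stricter filter (0.155), without overlapping genes (0.306), with an estimated correlation (0.307) and after the trend with gene length and score level was removed (0.239). The median of this list was -0.051 under the stricter filter, -0.07 with the trend removed and 0.022 without overlapping genes. Camera did not call the other 4 lists with scores as deposited (adjusted p = 0.213, 0.804, 0.175 and 0.804), and fry called the microglia markers and the endothelial and mural markers higher (0.00985 each). After centring each library on its median, 0 astrocyte markers rose and 10 fell, and rises and falls were 2 and 0 for microglia, 1 and 5 for oligodendrocyte lineage, 2 and 3 for endothelial and mural (2 and 1 with centring on the median deviation), and 0 and 5 for progenitor markers. Camera then called the astrocyte markers lower than other genes (0.00204), as after quantile normalization (0.00519) and centring on the median deviation (0.00209). With the latter and no pseudocount, 0 of 13 astrocyte markers rose and 0 fell.

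**Figure D1:**
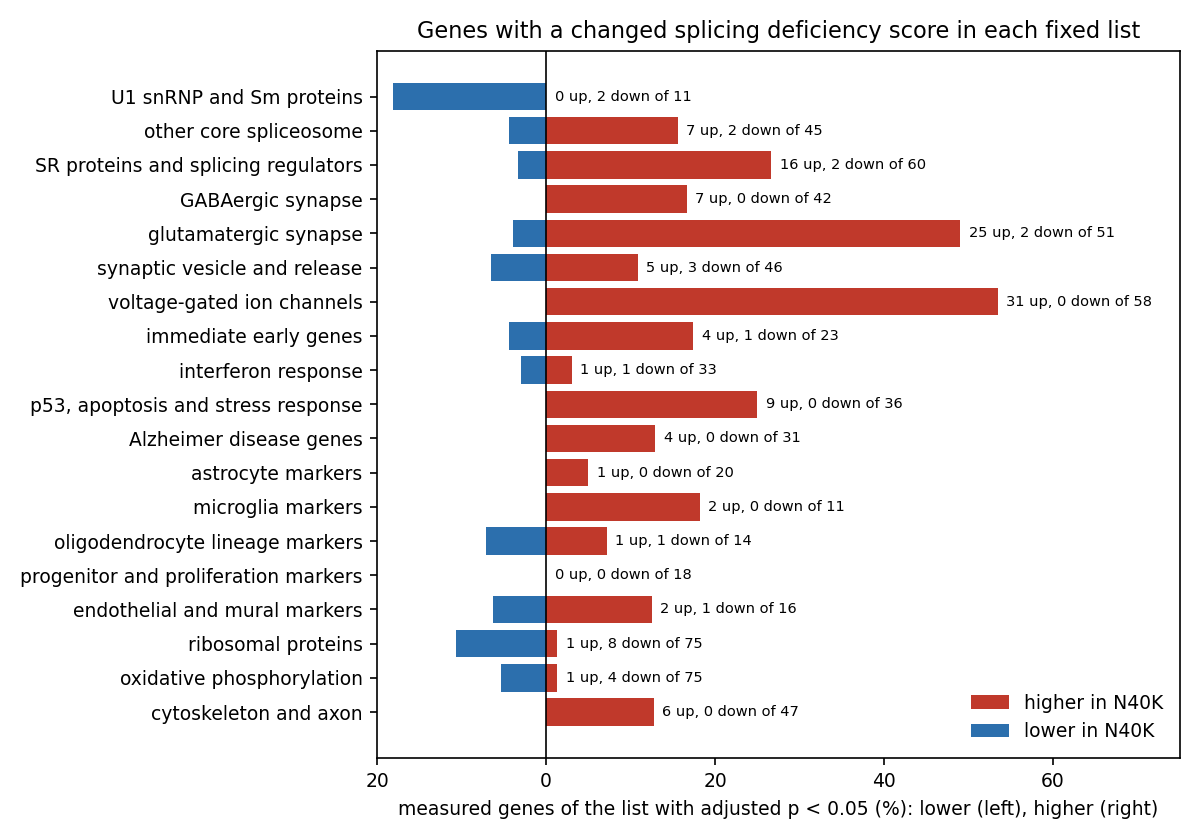
Percent of the measured genes of each of the 19 lists whose score was higher (right) or lower (left) in N40K than in control neurons at a limma adjusted p under 0.05, with scores as deposited; numbers beside the bars are gene counts. Glutamatergic synapse genes (25 of 51) and voltage-gated ion channels (31 of 58) had the highest shares of rises; with each library centred on its median, 4 and 6 of them rose and 10 and 11 fell, and after quantile normalization 14 and 19 rose and 6 and 5 fell.

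**Figure D2:**
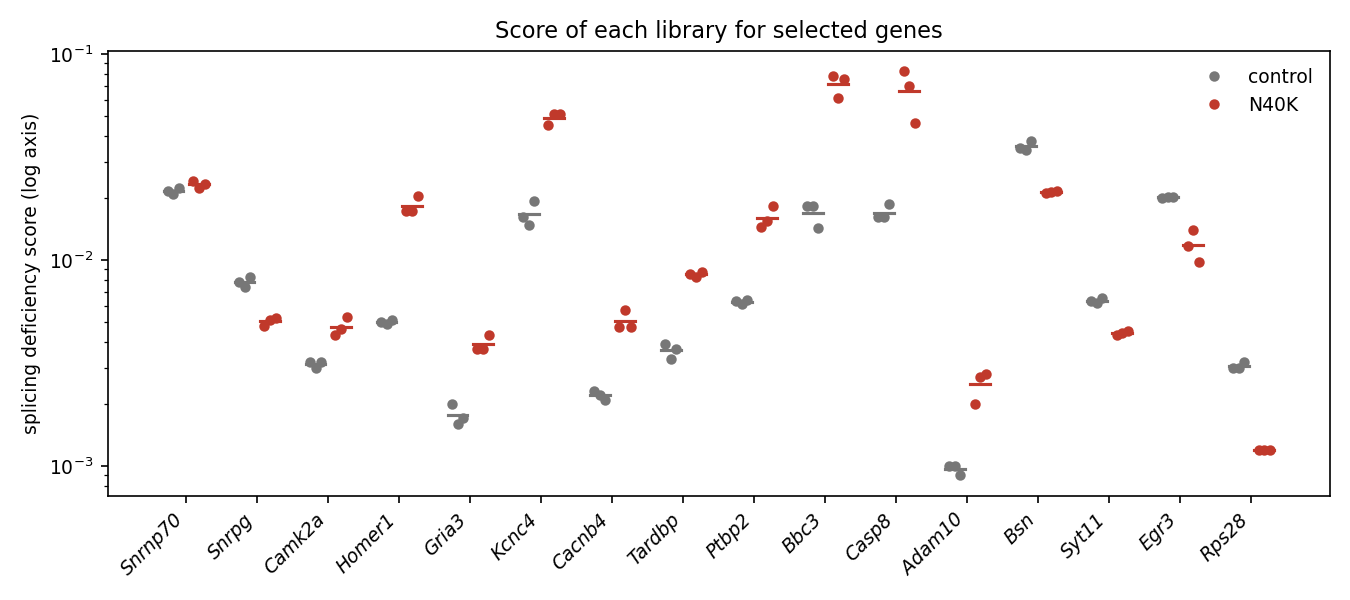
Splicing deficiency score (log axis) of 16 selected genes in each of the 3 control (grey) and 3 N40K (red) libraries; each point is a library and each bar the group mean. Snrnp70 did not pass the test, while Homer1 rose from 0.005 to 0.0183 and Bsn fell from 0.0356 to 0.0214.

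Longer genes rose more often. Annotated genes were divided by length into 8 classes of nearly equal size. In the shortest class, with a median length of 3.65 kb, 5.4% of genes rose and 6.2% fell. In the longest class, with a median length of 198 kb, 44.5% rose and 1.3% fell. The median ratio of mean scores increased from 0.996 in the shortest class to 1.44 in the longest, and the median log2 change, which the pseudocount reduces at the low scores of long genes, was -0.01 and 0.09. Across genes, which are not independent replicates, the log2 change had a Spearman rho of 0.244 with gene length and 0.171 with the number of introns. The rho was 0.181 with length given introns, and 0.042 with introns given length. Among genes with at most 3 introns 12.8% rose, and among genes with 17 or more introns 36.9% rose. Within a library, longer genes had lower scores, with a rho of -0.594 ± 0.0043 in control neurons and -0.538 ± 0.0147 in N40K neurons (SD, n = 3; exact permutation p = 0.1, the smallest possible). With each library centred on its median, 12.3% of the longest class rose and 23.6% fell, against 3.6% and 14.4% of the shortest class. In the longest class rises outnumbered falls under the other scalings: 27.7% and 7% after quantile normalization, 23.2% and 8.2% after centring on the median deviation, and 36.4% and 3.9% with the latter and no pseudocount. Without single libraries the share of rises in the longest class was 24.4%, 19.3% and 19.1% (controls 1, 2 and 3) and 24.9% (N40K 2). It was 25.9% with the eBayes trend off and 20% with the replicate number as a block.

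**Figure D3:**
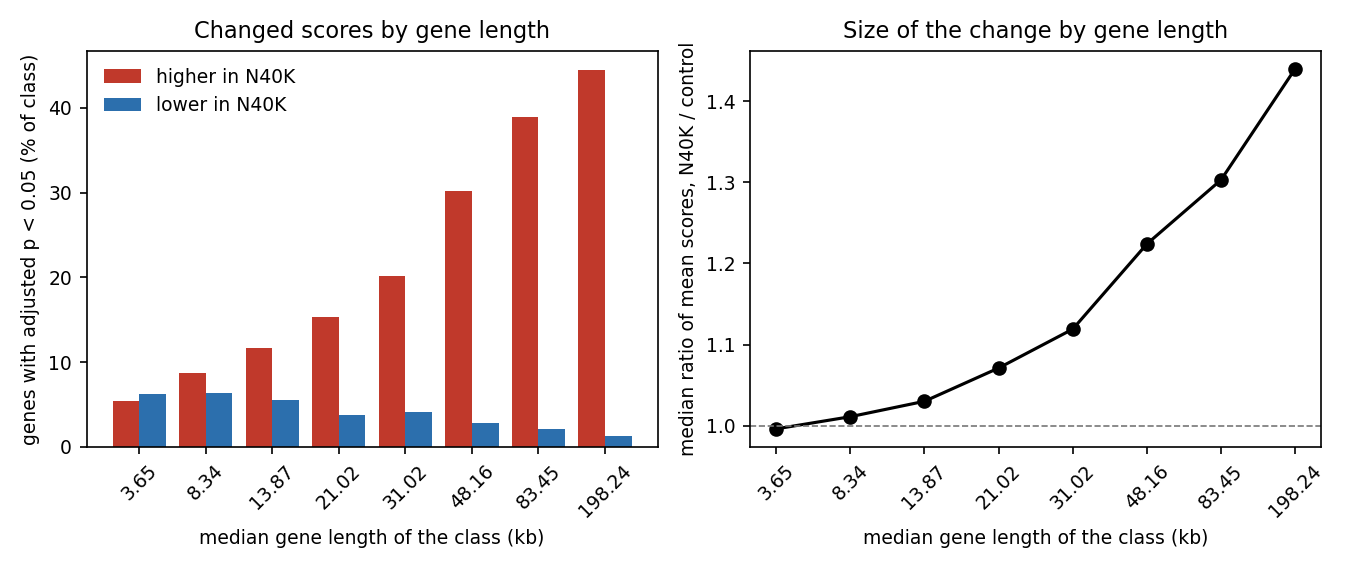
Percent of genes with higher or lower scores in N40K neurons (left) and median ratio of mean scores, N40K over control (right), in 8 classes of gene length, labelled by median length in kb, with scores as deposited. Rises went from 5.4% to 44.5% and falls from 6.2% to 1.3% between the shortest and the longest class; with each library centred on its median, falls outnumbered rises in both, while after quantile normalization 27.7% of the longest class rose and 7% fell.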

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

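The fits without a pseudocount, without overlapping genes and with centring on the median deviation were chosen only after the result was seen. So was the test of the lists with the length trend removed, except for the glutamatergic synapse and ion channel lists. The count of changed genes (4017) was 2451 under the stricter filter, which tests fewer genes, 951 at 1.5-fold, 1182 without overlapping genes, which tests 6082 genes, and from 1947 to 4215 when 1 library was left out. Same-numbered samples did not deviate together (correlations of -0.071, 0.038 and -0.02), so the scores show no pairing by number. The labels state no pairing, and this check cannot exclude that same-numbered samples were prepared together. With the replicate number as a block 2098 genes were called, and the shift of library medians kept its 0.13 with an exact sign-flip p of 0.25, the smallest possible. That shift ranged from 0.0278 to 0.207 (log2) with the pseudocount and from 0.105 to 0.153 with a library left out. Of the 19 lists, 6 were called, against 2 under the stricter filter, 11 after quantile normalization, 3 without overlapping genes, 3 others with the trend of gene length and score level removed, 0 with an estimated correlation, 7 by fry and 4 to 8 with a library left out; except where fewer genes were tested, the cause was not tested. The correlation of change with gene length was 0.153 to 0.359 over all alternatives run and 0.209 to 0.267 with a library left out, and that with intron number 0.125 to 0.225 and 0.16 to 0.177. The planned filter removed no gene, so leaving it out moved nothing.

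Values that reversed were these. The cause was not tested beyond the shift that centring removes, which is set below against the log2 changes. With each library centred on its median, the log2 change was -0.02 for Rims2 (-0.018), -0.056 for Slc1a2, -0.076 for Mtap1b, -0.064 for Kif1b and -0.053 for Snrnp70. As deposited, their changes with the pseudocount were 0.112, 0.075, 0.054, 0.066 and 0.077, all below the 0.13 removed. The ratios of mean scores of Rims2, Mtap1b and Kif1b were 2.3, 1.86 and 1.38, above the 1.17 of library medians. Their turn under this centring thus rests on the pseudocount, which reduces changes at low scores. Quantile normalization gave -0.012 for Slc1a2 and -0.063 for Snrnp70, centring on the median deviation -0.011 for Mtap1b, and the same without a pseudocount -0.04 for Snrnp70. None passed. For lists, the camera direction relative to other genes turned, with no adjusted p under 0.05, at these list medians: SR proteins and splicing regulators at -0.064 (library median), -0.01 (quantile), 0.001 (median deviation), 0.052 (the same without a pseudocount), 0.024 (without overlapping genes) and -0.023 (length trend removed); oxidative phosphorylation at -0.009 (length trend removed); glutamatergic synapse at -0.026 (library median); p53, apoptosis and stress response at 0.047 (stricter filter), -0.045 (quantile), -0.045 (median deviation without a pseudocount), 0.074 (without control 2) and 0.058 (without N40K 1); Alzheimer disease genes at 0.096 (stricter filter) and 0.04 (without overlapping genes); GABAergic synapse at 0.014 (without N40K 1; lowest with a library left out 0.012) and 0.017 (without overlapping genes). Fry, which tests a list by itself, gave another direction than camera for other core spliceosome (0.021), GABAergic synapse (0.017), synaptic vesicle and release (0.015), immediate early genes (-0.048), Alzheimer disease genes (0.027), astrocyte markers (-0.007), oligodendrocyte lineage markers (-0.027) and cytoskeleton and axon (0.002), none called by either. Of 450 values of the 75 named genes with a library left out, 393 kept direction and side of the threshold, 57 lost the call and 0 reversed; 18 of the 72 called genes lost the call without at least 1 library, and 13 lost it or turned after centring on the library median. Depth is unknown, so its limits cannot be given.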

Other observations

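The tests of 10 further gene lists and of gene-name families, of smaller error and of the pseudocount behind the length trend, of a single factor for every gene, and of lists other than the synapse and channel lists after the length trend was removed were chosen only after the result was seen. Genes of chromatin and genome maintenance had some of the highest shares of rises among these lists. Of 71 chromatin modifier genes, 39 rose and 0 fell; the histone methyltransferase gene Suv39h1 rose 2.53-fold and the demethylase gene Kdm5a 2.08-fold. Of 58 DNA repair genes, 27 rose and 2 fell (Ercc8 and Xpa); Brca2 rose from 0.0422 ± 0.00257 to 0.136 ± 0.0102 and Fancc from 0.00443 ± 0.00116 to 0.035 ± 0.00167. Of 29 nuclear pore and mRNA export genes, 11 rose, among them Nup85 (1.85-fold) and Ranbp2 (1.91-fold). Of 33 genes of cilia 12 rose, of 31 cadherins and protocadherins 11, of 19 cleavage and polyadenylation genes 7, of 44 autophagy and lysosome genes 10, of 24 cholesterol synthesis genes 5 and of 19 glycolysis genes 3, with 0 falls in each, and of 31 proteasome genes 4 rose and 1, Psmc1, fell. Camera called chromatin modifiers, cadherins, nuclear pore, DNA repair and cilia higher than other genes (adjusted p = 0.000196, 0.00296, 0.00666, 0.0165 and 0.0165), and with an estimated correlation called none of the 10 (adjusted p of 0.741 to 0.779). After the trend of change with gene length and score level was removed none of these 5 was called (0.493, 0.937, 0.558, 0.176 and 0.558). With each library centred on its median, 15 chromatin modifiers rose and 8 fell, and 14 DNA repair genes rose and 5 fell; rises and falls were 8 and 2 for cilia, 5 and 1 for nuclear pore, 6 and 2 for cleavage and polyadenylation, 4 and 7 for cadherins, 2 and 8 for autophagy and lysosome, 0 and 4 for cholesterol synthesis, 2 and 9 for glycolysis and 1 and 10 for proteasome. Other scalings changed some of these: quantile normalization and centring on the median deviation gave 9 and 0, and 7 and 1, for cadherins, 5 and 6, and 4 and 4, for autophagy and lysosome, and 2 and 3, and 4 and 1, for cholesterol synthesis. Centring on the median deviation without a pseudocount gave 2 and 0 of 15 for glycolysis and 3 and 2 of 25 for proteasome. With a library left out the lowest count of rises was 13 for chromatin modifiers and for DNA repair, 7 for cilia, 6 for cadherins, 6 for nuclear pore, 2 for cleavage and polyadenylation, 4 for autophagy and lysosome, 3 for cholesterol synthesis, 2 for glycolysis and 0 for proteasome. Among 78 families of genes sharing a name prefix, Nup (11 of 20 rose) and Usp, deubiquitinating enzymes (19 of 46 rose), were called higher (adjusted p = 0.0102 each), and Rps (5 of 43 rose, 4 fell) and Rpl (2 of 47 rose, 5 fell) lower (0.0366 and 0.0416). None was called with an estimated correlation (0.996).

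Longer genes rose more often, and smaller errors of longer genes would raise their call rate without a larger change. The median SE of a gene was 0.113 in the shortest class and 0.032 in the longest. The median log2 score of the longest relative to the shortest class was higher in N40K by 0.103 (SE 0.046 over libraries). With 3 libraries per group this argues only weakly against error as the whole cause. From the 6th class to the longest, the median log2 change went from 0.107 to 0.092 and its SE from 0.059 to 0.032. Rises went from 30.2% to 44.5% and the median ratio of mean scores from 1.22 to 1.44. A test of score level or pseudocount fixed before its result did not exclude them: the lowest correlation of change and length within the 4 classes of the mean score, with no pseudocount, was 0.178, below the 0.521 reached in some class in another split, although those splits mix the groups and a correlation does not measure the size of a change. In a second test, run because the first left the matter open, the slope of log2 score on log10 length without a pseudocount was higher in N40K in each of the 4 classes, by 0.221 (SE 0.056) in the class closest to its error, which argues against the pseudocount alone. Within the classes the rho of length with score was -0.311 to -0.142, and without a pseudocount the rho of change with score was -0.11 to -0.048 (over all genes -0.218, or -0.025 with the pseudocount). Score level cannot be told apart by the bound set beforehand, and an effect of N40K on longer transcripts remains a hypothesis that may hold beside it.

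The glutamatergic synapse and ion channel lists may stand out because their genes are long. With scores as deposited, 44.5% of all genes in the longest length class rose, and 38.9% in the class below it, against 49% and 53.4% of these lists. This comparison is not matched on length. The lists have median gene lengths of 121386 and 120387 nt, close to the 116241 nt at which the longest class begins. After the trend of change with gene length and score level was removed, the median log2 changes of their genes with a known length went from 0.104 to 0.003 and from 0.073 to 0.01, and the larger camera p of the pair was 0.551. The interquartile ranges over genes went from 0.099 to 0.094 and from 0.176 to 0.107, so the calls ended because the medians came close to 0, not because the spread grew. Both medians stayed just above 0, so gene length and a feature of these synaptic genes cannot be told apart by the bound set beforehand. Camera called neither list with the trend removed (adjusted p = 0.654 and 0.474), so no rise of these lists beyond it was found. On the same scale synaptic vesicle, astrocyte and cytoskeleton genes lay below the trend (adjusted p = 0.000506, 0.0192 and 0.0164), with none called at an estimated correlation (0.782 each).

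The higher scores over all genes together may come from scaling, from unspliced RNA or from N40K itself. A single factor for every gene, as from scaling of the libraries or a larger share of unspliced RNA, would move ribosomal protein and oxidative phosphorylation genes as much as others, but their median log2 ratio was -0.025 against 0.148 over all genes. Taken per library from the deviations of genes from their means, the difference was -0.207 (SE 0.038), and from library medians, computed first, -0.264. These lists were chosen for the test after camera had called them lower than other genes in the same data. A lower value was therefore known in advance, and the test cannot decide against scaling or unspliced RNA. It shows only that these lists did not rise with the other genes. How much of the shift is scaling cannot be told apart from a true shift: after centring each library on its median 34.7% of the called genes were higher in N40K, against 83.9% as deposited, which is neither the about equal numbers predicted for scaling nor past the bound set against it, and centring itself fixes this balance. Of the scalings run, only centring on the library median gave more falls than rises. It removed 0.13 (log2), where the median change of a gene was 0.06. Centring on the median deviation, chosen after seeing the data, gave 2235 rises and 1518 falls, and 2190 and 1202 without a pseudocount. That centring also sets the typical gene near 0, so it cannot give its direction. The direction of the typical gene therefore rests on how the scores were scaled, and the viruses also differ in carrying EGFP or N40K.

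The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For called genes 1 split, the real one, gave 4017, and the highest of the others gave 0. For called lists 2 splits gave at least the 6 of the real one, and the highest of the others gave 8.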
